A study of Mus musculus with 12 samples.

How the data were processed

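Messenger RNA of mouse cardiac fibroblasts was measured in 12 libraries, 6 control and 6 Pfas CKO, each from 1 µg of total RNA enriched with oligo(dT) beads, per the labels' protocols. Tamoxifen was given 7 and 3 days before infarction and 1 day after it, a schedule that the labels state for the Pfas CKO mice. Whether control mice were treated is not given in the sources used here, so an effect of tamoxifen cannot be told apart from that of the genotype. Samples were assigned to groups from the genotype in their labels.

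The deposited table holds 18771 genes with estimated counts, TPM and FPKM for each library, per the file headers. The estimated counts are reads per gene that need not be whole and were not normalized by the authors. The TPM values (transcripts, corrected for gene length) and the FPKM values (fragments per kilobase) were scaled per library by the authors, per the file headers. A further FPKM column holds the authors' mean of control 1 to 3 and was not used. Bowtie2, RSEM and DESeq2 are named, without versions or roles, in the submitters' processing notes for 9 libraries, and no tool is named for control 1 to 3. The build is GRCm38 for all libraries. The annotation, the strand setting and the filters are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Gene positions are from GENCODE M21 on GRCm38, matched by symbol, and 18714 of the 18771 gene IDs were found in the reference gene table.

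Values were blank in some control libraries for 1067 genes, 774 in control 1 to 3, 743 in control 4 to 6 and 450 in both, and for 0 genes in Pfas CKO. These genes were left out, since the sources used here do not say whether a blank is a count of 0, which left 17704. They held at most 0.0014% of a Pfas CKO library, and the highest count among them was 58.23. How the reads of near-identical genes were split is not given in the sources used here, and a different split in separately quantified sets would move counts from a gene to its copy.

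Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr on the group, glmQLFit and glmQLFTest, group as the only term), with Benjamini-Hochberg adjustment over 13600 genes and a threshold of 0.05. CPM values are TMM-scaled. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Gene lists were fixed before the data were examined, 36 in number. One of them, the mitochondrially encoded transcripts, had no member in the table, and 35 had at least 4 tested members. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with a correlation estimated per list, and with fry, and adjusted over the 35 lists. Counts of members refer to adjustment over all genes, and those adjusted over the list alone were the same unless given. Camera called 15 lists, and matrix remodelling, glycolysis, hypoxia and the immediate early genes were those still called with an estimated correlation.

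The genes named were Pfas, Peg3, the 8 largest folds in each direction among called genes with a mean of at least 2 CPM and a symbol that is not a clone name, and from each list the 3 called members with the smallest p, or the single smallest where the list was not called and had fewer than 3. A gene named by more than 1 part of the rule was counted under each. Not every gene that this rule takes is reported here.

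The test was checked on simulated counts for the Pfas CKO against control comparison, with 13530 genes, real means and library sizes, and 200 genes changed. It recovered 92.5% of 67 genes changed 1.5-fold, 98.5% of 67 changed 2-fold and 100% of 63 changed 4-fold. The simulated spread was a single value for all genes, set to that of the real libraries, and libraries were drawn independently. Unchanged genes made up 2.70% of the calls, the shifted list was called, and 0 of 30 random lists were. The real libraries form near-identical sets. Control 4 to 6 against control 1 to 3, of the same genotype, called 3228 genes higher and 3024 lower of 13727. The simulated shares therefore do not give the rate of false calls in the real libraries.

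Alternatives fixed before the data were examined were RLE scaling, library totals alone, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, no filter, a minimum mean of 5 CPM, a replicate block, each library or control set left out, 1 surrogate variable from sva 3.50.0, a macrophage marker covariate, X and Y genes left out, and other thresholds. Added after seeing the data were near-identical libraries summed, where the mean chi-square per gene (12739 genes with a mean count of at least 20) was under 10, and Pfas CKO 2 and 4 left out.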

Results

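RNA sequencing was used to profile cardiac fibroblasts, the matrix-producing stromal cells of the heart, isolated from the left ventricle of mice 3 days after myocardial infarction, which was made by tying off the left anterior descending artery for good. The study asked what Pfas does in these cells in vivo. Pfas encodes phosphoribosylformylglycinamidine synthase, an enzyme of de novo purine synthesis. The 6 control libraries came from mice carrying a tamoxifen-inducible Cre recombinase at Pdgfra, a gene expressed in fibroblasts, and a single floxed Pfas allele. Whether these mice also received tamoxifen is not given in the sources used here. The 6 knockout (Pfas CKO) libraries came from mice with the same Cre and both Pfas alleles floxed. Each library held between 20320133 and 20950074 estimated read counts, so a count of 0 (floor of 3 counts) allowed a level of up to 0.131 to 0.134 CPM in control and 0.157 to 0.161 CPM in Pfas CKO, limits that cover counting error only. Nothing in the labels says that the libraries of a group came from separate mice, and p-values therefore measure the spread between these libraries, which may be technical.

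The libraries fell into sets that were much closer to each other than to the rest of their group. Control 1 to 3 formed a set, control 4 to 6 another, and Pfas CKO 1, 3, 5 and 6 one more, while Pfas CKO 2 and Pfas CKO 4 each stood apart. Between libraries of a set the mean chi-square per gene was 1.68 to 5.22, where 1 is sampling noise alone. Across sets of a group it was 17.55 to 39.88, and between the groups it was 168.88 to 253.24. Libraries of a set thus differed by more than sampling noise, which does not show that they came from separate mice. They were kept as separate libraries in the main test, so n = 6 counts libraries. Control 1 to 3 also differed from all other libraries in the share of values without decimals. Between 60.8% and 61.5% of the non-zero values of control 1 to 3 were whole numbers (within 0.005), against 17.1% to 18.0% in control 4 to 6 and 19.6% to 26.3% in Pfas CKO. In this share control 4 to 6 lay close to Pfas CKO, though these libraries differed in blank values. No near-identical set held both groups. The submitters' notes name the same tools for control 4 to 6 and Pfas CKO, and none for control 1 to 3. Whether control 4 to 6 and Pfas CKO were prepared together is not given in the sources used here. A difference in processing between them and the genotype therefore cannot be told apart.

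The targeted transcript was lower in each Pfas CKO library than in each control library. Pfas (gene ID 237823; GRCm38 chromosome 11, 68985697 to 69008460, minus strand, protein-coding) stood at 23.3 ± 0.861 CPM in control and 11.2 ± 3.78 CPM in Pfas CKO (mean ± SD, n = 6 each), or 48.2% of the control level. Its log2 fold change was -1.05 ± 0.156 (SE), with an adjusted p of 2.26e-05 by the edgeR quasi-likelihood test. The control mice carried a single floxed Pfas allele, and macrophage transcripts were abundant in all libraries. The 48.2% is therefore not a measure of how much Pfas the fibroblasts lost. An exact two-sided permutation test on log2 CPM gave p = 0.00217, the smallest value that its 924 permutations can give. It takes the libraries as independent, which the near-identical ones are not, so this p overstates the evidence. With each near-identical set summed, the log2 fold change of Pfas was -0.80 (edgeR adjusted p = 0.0217). The remaining level was uneven, at 17.4 CPM in Pfas CKO 2 and 14.5 CPM in Pfas CKO 4 against 8.01 to 9.66 CPM in the other 4 libraries. Peg3, also called Pw1, is the imprinted gene in the title of the series (gene ID 18616; GRCm38 chromosome 7, 6703892 to 6730431, minus strand, protein-coding). It rose from 4.95 ± 0.444 to 10.7 ± 1.27 CPM (n = 6 each; log2 fold change 1.11 ± 0.0931, edgeR adjusted p = 5.21e-08).

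**Figure D1:**
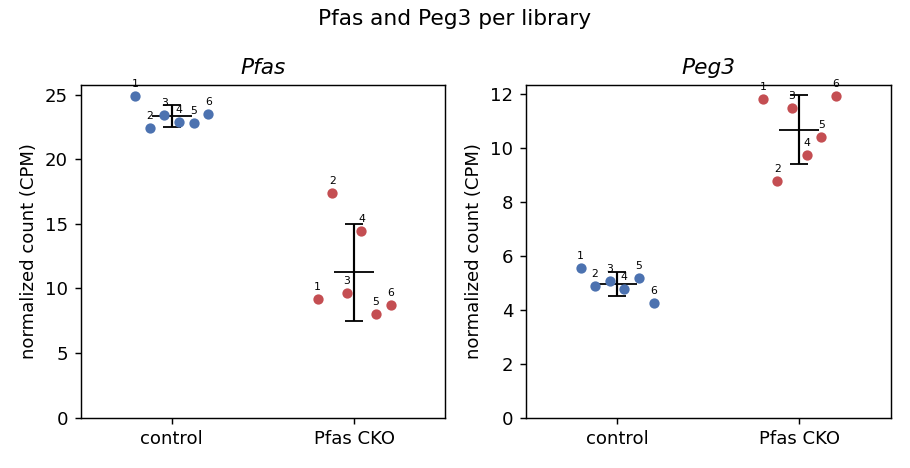
Normalized counts (CPM, linear axes from 0) of Pfas and Peg3 in the 6 control and 6 Pfas CKO libraries; points are libraries marked by replicate number, and black bars are the mean ± SD. Pfas lies between 8.01 and 17.4 CPM in Pfas CKO and above 22 CPM in control, while Peg3 is higher in Pfas CKO.

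Of 13600 genes tested, 4545 were higher and 4785 lower in Pfas CKO at an edgeR adjusted p under 0.05, and 935 and 851 of them had a fold of at least 2. With each set of near-identical libraries summed into 1 sample (2 control and 3 Pfas CKO samples), 2783 genes were higher and 2877 lower. Of the 1786 genes with a fold of at least 2, 1723 were still called in the same direction. Scaling by library totals alone gave 2775 higher and 7202 lower (625 and 1405 with a fold of at least 2), because it shifted the median of all genes from -0.02 to -0.26 on the log2 scale. It also lowered the median of each of the 35 gene lists by 0.230 to 0.234, and 6 medians turned from above to below 0, none of them in a called list. With log2(TPM + 1), which also changed the test, the filter and the correction for gene length, 2279 were higher and 7280 lower (401 and 919 with a fold of at least 2). Directions are given relative to the TMM scaling. Against control 1 to 3 alone 4610 genes were higher and 4641 lower, and against control 4 to 6 alone 4296 and 4466. As a background, control 4 to 6 were compared with control 1 to 3 in the same way. There 3228 genes were higher and 3024 lower of 13727, but only 100 had a fold of at least 2. The SD of the log2 differences over genes was 0.287 between the control sets and 0.768 between the groups.

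Inflammatory mediators rose. Of 33 cytokines, chemokines and related genes, 27 rose, 4 fell and 2 did not pass, with a median log2 fold change of 1.71. Tnf, a pro-inflammatory cytokine, rose from 37.9 ± 2.60 to 2980 ± 298 CPM (78.7-fold; n = 6 each). Cxcl2, a neutrophil-attracting chemokine, rose from 194 ± 31.7 to 6885 ± 1341 CPM, and Lif, a cytokine of the IL-6 family, from 184 ± 5.91 to 828 ± 64.8 CPM. Their edgeR adjusted p-values were 1.97e-16, 2.45e-13 and 7.43e-14. Il10, an anti-inflammatory cytokine outside this list, rose from 3.49 ± 0.755 to 912 ± 171 CPM. Slamf1 and Tarm1, receptors of activated leukocytes, rose from 0.341 ± 0.0371 to 25.5 ± 6.99 CPM and from 2.45 ± 0.360 to 126 ± 14.1 CPM. The list was called by camera with a preset correlation (adjusted p = 5.15e-09) but not with an estimated correlation (adjusted p = 0.132). The same list was also higher in control 4 to 6 than in control 1 to 3, by a median of 0.23 (camera adjusted p = 2.86e-06). Neutrophil and erythrocyte markers were higher as lists in the same libraries, with medians of 1.39 and 3.83, though 2 of 10 and 1 of 6 fell. Neither was called by camera with an estimated correlation (adjusted p = 0.555 and 0.0994).

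**Figure D2:**
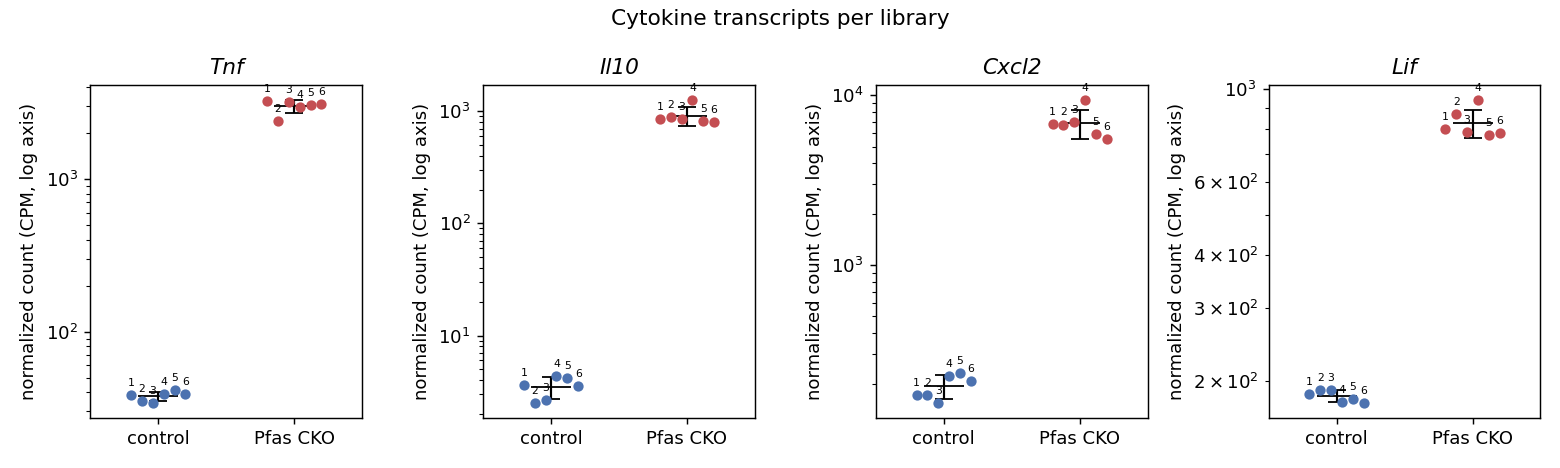
Normalized counts (CPM, log axes) of Tnf, Il10, Cxcl2 and Lif in the 6 control and 6 Pfas CKO libraries; points are libraries marked by replicate number, and black bars are the mean ± SD. For each gene, the Pfas CKO libraries lie above the control libraries with no overlap, as for Tnf at 37.9 against 2980 CPM on average.

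The rise in inflammatory genes was not matched by the macrophage markers as a group. Transcripts of macrophages were abundant in all libraries, and the 22 markers summed to a median of 10896 CPM in control and 11636 CPM in Pfas CKO. Of these markers 11 rose and 8 fell (camera adjusted p = 0.627). Cd14, a co-receptor for bacterial lipopolysaccharide, rose from 385 ± 34.4 to 1546 ± 145 CPM. C1qb, a complement subunit, rose from 167 ± 5.80 to 583 ± 127 CPM, and the Fc receptor gene Fcgr3 fell from 191 ± 24.5 to 69.5 ± 5.89 CPM (n = 6 each). Type I interferon response genes moved the opposite way to the cytokines. Of 32 genes, 21 fell and 6 rose (22 and 6 adjusted over the list alone), with a median of -0.70, which is unchanged when Ifi44l is placed at its bound. The antiviral gene Oas2 fell from 82.2 ± 2.16 to 24.6 ± 5.88 CPM, and Irf9, a subunit of the interferon-activated transcription factor, from 87.7 ± 3.49 to 53.2 ± 2.89 CPM. Ifi44l was at 3.18 ± 0.438 CPM in control and had no count in any Pfas CKO library, at least 19.98-fold lower against a floor of 3 counts per library. The fall was deeper in Pfas CKO 2 and 4, with mean log2 levels of 5.16 and 4.82 against 5.68 to 5.71 in the other 4 and 6.06 to 6.15 in control, and without these libraries the median was -0.45 and 10 genes rose (camera adjusted p = 0.0211). The camera adjusted p of the list was 0.00536, it was 0.713 with an estimated correlation, and on log2(TPM + 1) the call was lost (adjusted p = 0.0876; 8.70e-06 to 0.0901 over 28 alternative settings).

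Hypoxia and glycolysis genes rose together, but the lists share Slc2a1, Ldha and Pdk1, so their rises are not independent. Of 19 hypoxia targets, 18 rose and none fell, with a median log2 fold change of 1.09 (camera adjusted p = 1.40e-09; 0.0356 with an estimated correlation). Ankrd37 rose from 2.01 ± 0.258 to 18.6 ± 1.54 CPM, and Ndrg1, a stress-responsive gene, from 314 ± 10.6 to 793 ± 27.5 CPM (n = 6 each). Of 22 glycolysis genes, 18 rose and 1 fell, with a median of 0.76 (camera adjusted p = 2.32e-08; 0.04996 with an estimated correlation). Slc16a3, a lactate exporter, rose from 29.6 ± 3.21 to 179 ± 5.67 CPM. Tpi1, a glycolytic enzyme, rose from 173 ± 3.99 to 388 ± 5.79 CPM, and Pdk1, which restrains pyruvate oxidation and belongs to both lists, from 3.11 ± 0.417 to 20.5 ± 1.46 CPM. Pentose phosphate genes were not called as a list (4 higher and 1 lower of 8). Among them Pgd and Taldo1 rose by 0.75 and 0.65 on the log2 scale, and Rpia fell by 0.50. Nuclear-encoded oxidative phosphorylation genes were not called either (12 higher and 17 lower of 49), and with library totals alone 1 was higher and the median was -0.27 in place of -0.04. Ndufa9 and Ndufs8, of complex I, fell by 0.48 and 0.64, and Sdhb, of complex II, fell by 0.41. On log2(TPM + 1) that list was called lower (adjusted p = 0.0484; 0.0455 to 0.974 over 28 alternative settings). The immediate early and dissociation genes were higher in the same libraries, with a median of 0.80.

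Genes of the pathway that Pfas belongs to moved in different directions. Of 14 de novo purine synthesis genes, 4 rose and 6, with the deleted Pfas among them, fell, and the list was not called (camera adjusted p = 0.591). With library totals alone 1 was higher and the median was -0.31, and with near-identical libraries summed 1 was higher and 4 lower. Impdh2, which commits inosine monophosphate to guanine nucleotides, rose from 72.6 ± 4.49 to 125 ± 8.92 CPM. Gart and Atic, the pathway enzymes that use folate cofactors, fell from 57.7 ± 4.10 to 34.8 ± 3.15 CPM and from 77.4 ± 3.53 to 50.6 ± 4.95 CPM (n = 6 each). Of 27 purine salvage and breakdown genes, 8 rose and 17 fell (camera adjusted p = 0.216). Ampd3, an AMP deaminase, rose 4.03-fold, and the adenylate kinase gene Ak4 rose 3.64-fold. Ada, adenosine deaminase, fell from 62.4 ± 3.97 to 18.98 ± 1.40 CPM. Of 20 pyrimidine synthesis genes, 4 rose and 12 fell (camera adjusted p = 0.0759), and the list was called without Pfas CKO 2 (adjusted p = 0.0426), without control 1 to 3 (0.0439), without a filter on low counts (0.0485) and with library totals alone (0.0452; 0.0426 to 0.148 over 28 settings). Uckl1, Ctps2 and Dhodh in that list fell by 0.79, 0.64 and 0.81. Folate and serine one-carbon genes were lower as a list, with 16 of 23 down and 3 up and a median of -0.36 (camera adjusted p = 0.00742; 0.442 with an estimated correlation), or -0.59 with library totals alone. The fall was smaller in Pfas CKO 2 and 4, with mean log2 levels of 4.27 and 4.20 against 3.99 to 4.07 in the other 4 and 4.39 to 4.43 in control, and without these libraries the median was -0.50. Mtr, methionine synthase, fell from 24.0 ± 0.791 to 13.9 ± 1.14 CPM. Its reactivating enzyme Mtrr fell by 0.80, and Mthfd1, which interconverts folate cofactors, fell by 0.66.

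Collagen genes moved in different directions, and genes of matrix remodelling were higher as a list. Col1a1 fell from 4397 ± 862 to 2279 ± 236 CPM and Col1a2 from 4287 ± 331 to 2927 ± 186 CPM, whereas Col12a1 rose from 103 ± 3.15 to 137 ± 5.55 CPM (n = 6 each). Col12a1 did not pass on log2(TPM + 1) (adjusted p = 0.0580; 4.15e-25 to 0.0580 over 28 settings). Collagens as a list were not called, with 5 up and 6 down of 20 (5 and 5 adjusted over the list alone; camera adjusted p = 0.796). The collagens also differed between the control sets, with 17 of 20 lower in control 4 to 6 and a median of -0.29 (camera adjusted p = 2.18e-07). Of 48 matrix proteins and remodelling genes, 30 rose and 8 fell, with a median of 0.30 (camera adjusted p = 0.00536; 0.0378 with an estimated correlation). With library totals alone its median was 0.06 and 21 rose. Thbs4, a thrombospondin, rose from 10.8 ± 0.798 to 125 ± 35.5 CPM. Adamts1 and Mmp14, both matrix-cleaving proteases, rose 1.89-fold and 1.91-fold. Markers of resting cardiac fibroblasts rose in 18 of 24 genes and fell in 3, with a median of 0.43 (camera adjusted p = 0.00227; 0.326 with an estimated correlation), or 0.20 with library totals alone. Gfpt2 rose from 336 ± 6.99 to 763 ± 70.4 CPM, Cd34 from 78.9 ± 1.43 to 175 ± 31.2 CPM and the transporter gene Abca8a from 19.99 ± 1.07 to 61.0 ± 14.7 CPM. Among those that fell, singled out after their values were seen, were Pdgfra, the Cre driver gene, from 209.8 ± 8.14 to 121.2 ± 28.6 CPM and Ly6a from 238.9 ± 14.5 to 148.6 ± 21.6 CPM. Endothelial and cardiomyocyte markers were higher as lists in the same libraries, with medians of 0.54 and 1.00. Neither was called by camera with an estimated correlation (adjusted p = 0.265 and 0.0532).

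Contractile and TGF-β genes were not called as lists. Of 24 myofibroblast contractile genes, 11 rose and 8 fell (camera adjusted p = 0.495), and with library totals alone 6 were higher and the median turned from 0.11 to -0.12. Tagln2 rose from 259 ± 12.4 to 497 ± 28.9 CPM, Tpm4, a tropomyosin, rose by 0.46 on the log2 scale, and Cnn2, a calponin, fell by 0.60. Cnn2 did not pass with the near-identical libraries summed (adjusted p = 0.0578; 1.47e-08 to 0.0578 over 28 settings). Of 28 TGF-β ligands, receptors and feedback targets, 16 rose and 6 fell (camera adjusted p = 0.109, and 0.0433 without Pfas CKO 2 and 4; 0.0433 to 0.242 over 28 settings). With library totals alone 9 were higher and the median was 0.00112 in place of 0.23. Skil and Tgif1, co-repressors of SMAD signalling, rose by 1.26 and 0.65, and Tgfbi, a secreted matrix protein, fell by 0.75.

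Immediate early genes rose, and p53 targets were higher as a list. Of 26 immediate early and dissociation genes, 22 rose and 1 fell (22 and 2 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 4.58e-08; 0.00282 with an estimated correlation). Junb, an AP-1 subunit, rose from 225 ± 14.3 to 696 ± 20.2 CPM, Ier3 from 200 ± 11.7 to 1185 ± 172 CPM, and Atf3, a stress-induced transcription factor, from 257 ± 4.91 to 661 ± 40.0 CPM (n = 6 each). Of 25 p53 targets, 16 rose and 5 fell, with a median of 0.30 (camera adjusted p = 0.00596; 0.0783 with an estimated correlation). With library totals alone the p53 median was 0.06 and 10 rose. Gdf15, a stress-induced cytokine, rose from 14.1 ± 0.903 to 244 ± 67.8 CPM, Plk2 rose 2.71-fold, and the cell-cycle inhibitor Cdkn1a rose from 236 ± 15.4 to 487 ± 13.5 CPM. The ATF4 list was split, with 12 up and 13 down of 30 (camera adjusted p = 0.939) and a median of -0.08 beside a mean of 0.00228, but with library totals alone 6 were higher and the median was -0.31. In it the cystine transporter gene Slc7a11 rose 4.95-fold and Cebpb 2.04-fold.

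Proliferation genes gave no common direction. Of 30 mitosis genes, 6 rose and 14 fell (camera adjusted p = 0.430). Mki67, a proliferation marker, rose from 90.7 ± 4.32 to 199 ± 7.02 CPM, the mitotic kinase gene Plk1 fell from 16.6 ± 1.60 to 9.66 ± 1.07 CPM, and Ccnf rose by 0.59 on the log2 scale. Of 36 S-phase genes, 8 rose and 6 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.660). Mcm3 and Ccne2 rose by 0.41 and 1.26, and Cdt1, a replication licensing factor, fell by 0.50. Ribosome biogenesis was split as well (15 up and 17 down of 45; camera adjusted p = 0.946), with Heatr1 and Rrp12 down by 0.92 and 0.70 and Rrs1 up by 0.55. With library totals alone 6 ribosome biogenesis genes were higher and the median was -0.27 in place of -0.04. Ribosomal protein genes rose in 62 of 73 and fell in 1 (64 and 1 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.59e-08; 0.442 with an estimated correlation). With library totals alone their median was 0.17 and 34 rose. Rpl29 and Rpl24 rose 1.63-fold and 1.51-fold. These genes have many processed pseudogenes, so their values are uncertain, above all that of Rpl34.

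Imprinted genes were higher as a list, with 11 up and 3 down of 18 and a median of 0.37 (camera adjusted p = 0.0387; 0.118 with an estimated correlation), or 0.14 with library totals alone. Besides Peg3, Plagl1, a zinc-finger regulator of other imprinted genes, rose from 31.7 ± 3.06 to 69.2 ± 5.05 CPM and Mest from 8.18 ± 1.03 to 21.9 ± 3.58 CPM (n = 6 each). The call was lost without Pfas CKO 4 (adjusted p = 0.0502), without control 4 to 6 (0.0713) and with a minimum mean of 5 CPM (0.0788), with a range of 0.0120 to 0.0788 over 28 settings. Genes beside Pfas on chromosome 11 were not called (5 up and 3 down of 12; camera adjusted p = 0.317). Borcs6, Ndel1 and Arhgef15 among them rose by 0.96, 0.42 and 0.67.

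Several marker lists of other cells of the infarcted heart differed between the groups. The 19 endothelial markers held 15 that rose and 3 that fell (median 0.54, or 0.30 with library totals alone; camera adjusted p = 0.00146; 0.265 with an estimated correlation). Cldn5, a tight junction gene, rose from 21.9 ± 0.813 to 44.4 ± 1.31 CPM, and Esam and Flt1 rose 1.81-fold and 1.52-fold. Among 19 cardiomyocyte markers, 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 1.00; camera adjusted p = 0.000758; 0.0532 with an estimated correlation). Actc1 rose from 3.42 ± 0.731 to 10.6 ± 0.310 CPM and Tnnt2 from 3.40 ± 0.609 to 8.89 ± 0.896 CPM, both genes of the contractile apparatus, and Atp2a2, also widely expressed, rose 1.34-fold. Among 6 erythrocyte markers, 5 rose and 1 fell (median 3.83; camera adjusted p = 0.00742; 0.0994 with an estimated correlation). Hbb-bs, a beta-globin gene, rose from 3.13 ± 0.544 to 81.7 ± 13.2 CPM. Among 10 neutrophil markers, 7 rose and 2 fell (median 1.39; camera adjusted p = 0.0387; 0.555 with an estimated correlation). S100a9 rose from 2.85 ± 0.506 to 34.0 ± 14.8 CPM and Hdc, histidine decarboxylase, from 3.35 ± 0.287 to 36.8 ± 5.87 CPM, while the collagenase gene Mmp8 fell from 154 ± 14.7 to 25.6 ± 7.78 CPM (n = 6 each). The neutrophil rise was larger in Pfas CKO 2 and 4, where S100a9 stood at 56.2 and 49.6 CPM against 23.7 to 25.6 CPM in the other 4. The neutrophil call was lost without Pfas CKO 2 (adjusted p = 0.0615), without control 4 to 6 (0.102) and with a minimum mean of 5 CPM (0.0906), and with that minimum the cardiomyocyte and erythrocyte calls were lost too (0.0859 and 0.0792). Over 28 settings the adjusted p ran from 0.00102 to 0.102 for neutrophil, 8.62e-06 to 0.0859 for cardiomyocyte and 0.000415 to 0.0792 for erythrocyte markers.

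Further marker lists were not called by camera. Pericyte and smooth muscle markers had 7 up and 2 down of 14 (adjusted p = 0.198), with Mcam up by 0.81, Abcc9 up by 0.45 and Cspg4 down by 0.86 on the log2 scale. Abcc9 did not pass with near-identical libraries summed (adjusted p = 0.0618) or on log2(TPM + 1) (0.138), and over 28 settings the adjusted p ran from 2.07e-06 to 0.140. Epicardial markers had 6 up and 2 down of 10 (adjusted p = 0.455), with C3 and Aldh1a1 up by 0.60 and 0.59 and Krt19 down by 1.18. Aldh1a1 did not pass on log2(TPM + 1) (adjusted p = 0.0515; 2.57e-09 to 0.0516 over 28 settings). Platelet markers had 3 up and 1 down of 6 (adjusted p = 0.277). The platelet chemokine genes Pf4 and Ppbp rose 2.72-fold and 3.11-fold, and Treml1 fell by 2.06. Lymphocyte markers had 2 up and 1 down of 6 (2 and 0 adjusted over the list alone; adjusted p = 0.660) at levels near 1 CPM. Cd8a rose from 0.547 ± 0.112 to 1.13 ± 0.388 CPM. Cd4 stood at 2.56 ± 0.527 and 1.73 ± 0.686 CPM, a log2 fold change of -0.57 that no longer passed without control 1, 5 or 6 or Pfas CKO 1, 2 or 4 (adjusted p between 0.0551 and 0.106; 0.00518 to 0.164 over 27 settings). Schwann and neuronal markers had 1 up and 1 down of 9 (none adjusted over the list alone; adjusted p = 0.796). Prnp in that list stood at 0.15 on the log2 scale, a difference that no longer passed without control 1, 2 or 3 or Pfas CKO 2, 3 or 4 (adjusted p between 0.0520 and 0.0804; 0.000782 to 0.495 over 28 settings). It turned to -0.08 with library totals alone and to -0.16 on log2(TPM + 1). The Y-linked gene Kdm5d fell by 0.67, and the sex marker list was not called (0 up and 1 down of 4; adjusted p = 0.591).

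**Figure D3:**
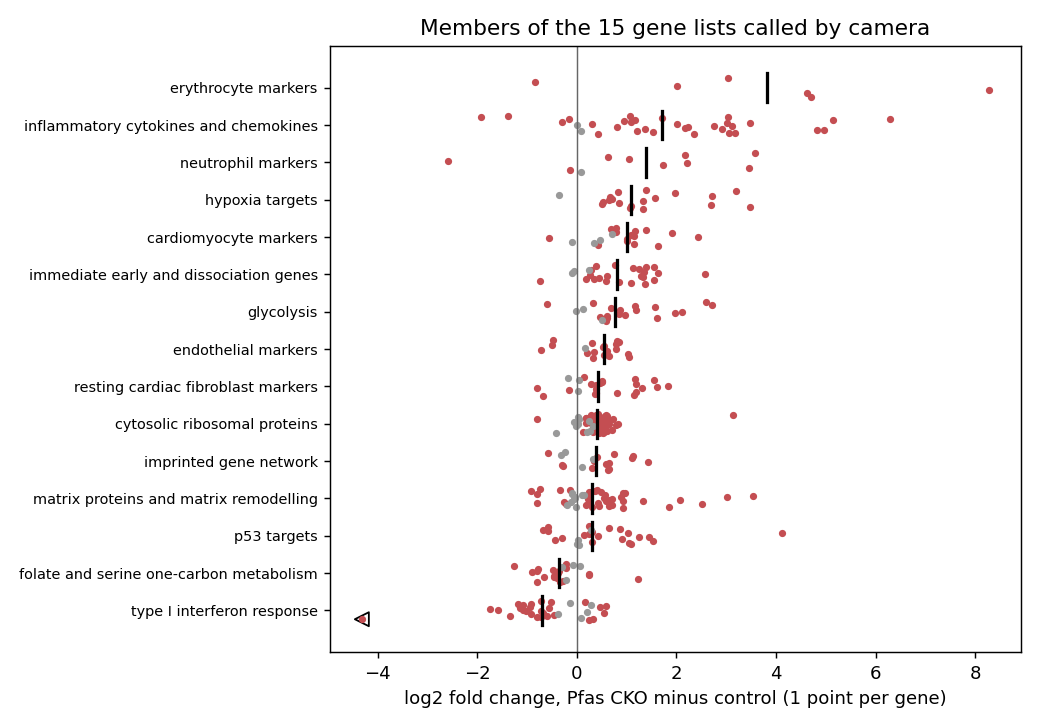
Log2 fold changes (Pfas CKO minus control, horizontal axis) of the members of the 15 lists called by camera with a preset correlation. Each point is a gene, red where its edgeR adjusted p is under 0.05 and grey otherwise, the black bar is the list's median, and the open triangle marks Ifi44l at its bound; medians run from -0.70 for interferon genes to 3.83 for erythrocyte markers.

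Several genes with the largest folds belong to families of near-identical copies, and their values are uncertain. Cd300ld5 had no count in any control library and stood at 8.26 ± 3.70 CPM in Pfas CKO, at least 61.96-fold higher against a floor of 3 counts per library. Hba-a2, an alpha-globin gene, stood at 0.134 ± 0.328 and 43.4 ± 8.28 CPM, beside its copy Hba-a1 at 5.32 ± 0.883 and 43.8 ± 5.51 CPM. Eif3j1 rose from 4.12 ± 1.64 to 149 ± 33.4 CPM. The pseudogene Rpl34-ps1 fell from 136 ± 8.61 to 0.159 ± 0.2495 CPM while Rpl34 rose from 23.2 ± 3.00 to 203 ± 27.5 CPM (n = 6 each). H2-Q8, Ceacam2, Trim34b and Ms4a4b fell from 10.97 ± 7.86, 6.70 ± 1.12, 4.06 ± 0.486 and 32.8 ± 5.85 CPM to 0.113 ± 0.277, 0.106 ± 0.1001, 0.0888 ± 0.154 and 1.23 ± 0.363 CPM. The control mean of H2-Q8 joins 17.4 to 18.9 CPM in control 1 to 3 with 2.99 to 5.54 CPM in control 4 to 6. Nlrp10, an NLR family gene, fell from 6.08 ± 0.255 to 0.239 ± 0.138 CPM. Csprs fell from 4.24 ± 1.32 to 0.195 ± 0.184 CPM and the zinc-finger gene Zfp985 from 5.40 ± 0.591 to 0.283 ± 0.227 CPM. For 4 of 8 such genes, Rpl34-ps1, Eif3j1, Ceacam2 and Ms4a4b, the copies in the table moved the other way and offset most of the gene's own change. Rpl34 and its pseudogene together stood at 159 ± 8.24 and 204 ± 27.7 CPM. For Hba-a2 and Trim34b the copies moved the same way. Hba-a2 and Hba-a1 together rose 15.99-fold, and Trim34b and Trim34a together fell 1.92-fold.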

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

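The tests of macrophages, neutrophils, library sets, handling, gene copies, linked DNA and other splits of the libraries were chosen only after the results were seen, whereas the tests of X-linked genes and of fibroblast share were written before their own values were computed, though after Pfas CKO 2 and 4 had been seen to stand apart and to have low Y-linked transcripts, and the control background of the former was added after its value was seen.

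The rise of inflammatory, hypoxia and glycolysis genes in Pfas CKO was weighed first. More macrophages of the kind present in the controls would raise their markers about as much as the inflammatory genes. The median of these 22 markers was only 0.1154 (SD over markers 0.929), against 1.714 for the inflammatory and 1.09 for the hypoxia genes. The 0.76 of the glycolysis genes lies within that spread, and the hypoxia median lies only just beyond it. That SD is the spread of single markers, not the error of their median, so it is a weak basis for treating hypoxia and glycolysis genes differently. More such macrophages stay open for the glycolysis genes. An activated subset of macrophages stays open. More neutrophils were not settled either. Their markers had a median of 1.387 that was not called by camera with an estimated correlation (adjusted p = 0.555), with S100a9 up to 34.0 CPM but Mmp8 down to 25.6 CPM. Summed, the neutrophil markers stood at a median of 667.9 CPM in control and 769 CPM in Pfas CKO, against 9447 and 37899 CPM for the inflammatory genes. The sum of the neutrophil markers thus rose far less than that of the inflammatory genes, unlike their median. Immediate early and dissociation genes had a median of 0.8049, and 0 of their 26 members are in those lists. A response to handling may contribute, but this list cannot tell it from a response that accompanies the inflammatory genes. The inflammatory list also differed by 0.2299 between the control sets. Without control 1 to 3, the medians were 1.602 for the inflammatory, 1.134 for the hypoxia and 0.7836 for the glycolysis genes. A processing difference confined to control 1 to 3 would therefore not give these rises. The submitters' notes name the same tools for the remaining controls and Pfas CKO, but whether these were prepared together is not given. A processing difference between them and the genotype therefore cannot be told apart. An effect of losing Pfas, or of tamoxifen if the controls had none, also stays open.

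The 16 genes of largest fold were weighed next. None of the 14 with an annotated position lay within 10 Mb of Pfas (0 genes), which argues against DNA that close to the floxed locus as their source. Hba-a2 and Cd300ld5 lie farther away on the same chromosome, and longer linked stretches were not tested. Within that distance 12.15% of 288 genes had a called fold of at least 2, against 12.89% of the rest. Reads shared between near-identical copies may account for 4 of the 8 genes with a copy in the table, where the copies moved the other way and left the sum changed by under 0.5 of the gene's own change, as for Rpl34-ps1 (-135.9 CPM, copy 180.1 CPM) and Eif3j1 (144.5 CPM, copy -105.4 CPM). The copies of Hba-a2 and Trim34b moved the same way, so shared reads alone would not give the change of their sums. Hba-a2 with Hba-a1 rose from 5.45 to 87.2 CPM (15.99-fold, against 311-fold for Hba-a2 alone). Trim34b with Trim34a fell from 18.5 to 9.63 CPM (1.92-fold, against 43-fold for Trim34b alone). A changed split of reads may therefore enlarge the folds of the single genes. H2-Q8 and Cd300ld5 are too low beside their copies to decide, and no biological explanation was tested.

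The separation of Pfas CKO 2 and 4 from the other 4 Pfas CKO libraries was weighed last. They had the most Pfas left, at 17.4 and 14.5 CPM against 8.01 to 9.66 CPM, for a reason that was not tested. Their inflammatory genes had the highest mean log2 levels, 8.484 and 8.641 against 8.267 to 8.315. Without them, however, the median log2 fold change of that list was 1.857, against 1.714 with all libraries. Ddx3y, a Y-linked gene, stood at 47.15 and 59.94 CPM in Pfas CKO 2 and 4 against 106.1 to 135.4 CPM in the other 4, and Eif2s3y at 28.77 and 32.2 CPM against 53.15 to 57.13 CPM. Uty and Kdm5d were lower there too (-0.75 and -0.52 on the log2 scale), and Xist was not in the table. Material from female mice mixed into both libraries could lower these Y-linked genes. The 5 X-linked genes that escape inactivation were higher there by a median of 0.2721, which met the bound written beforehand. All but Ddx3x were higher in both libraries than in each of the other 4. They were also higher in control 4 to 6 than in control 1 to 3, by a median of 0.23 (SD over genes 0.267), though Kdm5c was lower (-0.34). That background leaves the question open. Endothelial minus macrophage markers differed by -0.1118 (SE 0.1459), and endothelial (-0.22, SE 0.0789), macrophage (-0.11, SE 0.123) and resting fibroblast markers (-0.19, SE 0.141) were all lower in these libraries, so a changed share of fibroblasts was not shown and stays open. Sex of the animals is not in the labels used here, and no other biological explanation was tested.

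Of 298 groups of 6 values (named genes, list levels and library totals), 29 had a library whose gap to its nearest neighbour took up more of the range than Dixon's 95% critical value, where chance gives about 1 in 20. Pfas CKO 2 was that library in 15 of them and Pfas CKO 4 in 9, and 4 lay in control. In Pfas CKO 2, Tnf stood at 2410 CPM against 2940 to 3220 CPM in the other 5 libraries of its group. H2-Q8 had 0.679 CPM there and 0 in the others. Tgif1 was at 263 CPM against 290 to 307 CPM, and Plk2 at 1160 CPM against 1390 to 1530 CPM. Pgd was at 797 CPM against 688 to 720 CPM. Mest was at 14.9 CPM against 22.2 to 25.3 CPM, and Mmp8 at 41.3 CPM against 20.6 to 24.1 CPM. Abcc9 was at 15.6 CPM against 18.9 to 20.6 CPM, and Atp2a2 at 538 CPM against 557 to 568 CPM. Mean log2 levels of lists in Pfas CKO 2 were 5.38 for de novo purine synthesis against 5.27 to 5.28, and 4.74 for pyrimidine synthesis against 4.56 to 4.63. Collagens were at 8.15 against 8.21 to 8.25, and ribosomal proteins at 8.84 against 8.42 to 8.57. The pentose phosphate level was 6.65 against 6.48 to 6.54, and the imprinted level 4.80 against 4.90 to 4.93.

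In Pfas CKO 4, Il10 stood at 1260 CPM against 806 to 886 CPM in the other 5 libraries. Ak4 was at 89.3 CPM against 68.0 to 75.3 CPM, and Slc7a11 at 2150 CPM against 1370 to 1600 CPM. Heatr1 was at 82.3 CPM against 93.0 to 97.2 CPM, and Slc16a3 at 190 CPM against 175 to 179 CPM. Oas2 was at 13.7 CPM against 22.1 to 29.3 CPM, and Cd8a at 1.88 CPM against 0.848 to 1.15 CPM. C3 was at 534 CPM against 659 to 715 CPM, and the hypoxia list had a mean log2 level of 6.82 against 6.67 to 6.71. Ccnf in Pfas CKO 3 was at 35.0 CPM against 38.6 to 39.6 CPM. Among controls, Hba-a2 had 0.803 CPM in control 5 and 0 in the others, and Tgif1 194 CPM in control 5 against 185 to 188 CPM. Thbs4 was at 9.25 CPM in control 4 against 10.8 to 11.4 CPM, and Atf3 at 248 CPM in control 1 against 258 to 261 CPM. Myh4, blank in every control and so left out of the tests, had a mean of 16 counts in Pfas CKO (0 to 43.2), the only 1 of 450 such genes above 3 counts.

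Other splits of the 12 libraries into groups of 6 were also tested. Of 100 drawn from 462 splits, 1, the real one, gave as many as 9330 called genes, and the highest of the others gave 3984, but near-identical libraries are not independent, so this share overstates the evidence. Control 4 to 6 against control 1 to 3, which share a genotype, gave 3228 higher and 3024 lower. With the near-identical libraries summed, the 5 samples allow 10 splits, too few for a share under 0.05, and edgeR called 5660 genes in the real split and at most 0 in the others.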

How the results depend on the processing

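Summing near-identical libraries and leaving out Pfas CKO 2 and 4 together were chosen only after the data were seen; the other settings were not. Directions of Pfas and of the 15 called lists were the same under every setting run, with Pfas between -1.40 and -0.80 (library totals and TPM included). Scaling by library totals alone moved the counts to 2775 higher and 7202 lower (27.8% higher against 48.7%). With log2(TPM + 1) they were 2279 and 7280 and with log2(TPM + 0.1) 2271 and 7263, where the test, the filter and the length correction changed as well, so scaling alone is not shown to be the cause. The median of all genes was -0.26, -0.28 and -0.31. Prnp was reversed in these to -0.08136, -0.1627 and -0.1642. Summed libraries gave 2783 and 2877, fewer samples being tested, and kept 5367 of 9330 calls. A fold of at least 2 left 935 and 851, or 1025 and 927 with summed libraries and 625 and 1405 with library totals alone. Camera with an estimated correlation called 4 lists and fry 28, since fry does not compare a list with other genes. A minimum of 5 CPM gave 3628 and 3853, with 11 lists, fewer genes being tested. Without Pfas CKO 2 and 4 there were 4617 higher, 5141 lower and 16 lists. Leaving out 1 library at a time gave 4388 to 4535 higher, 4575 to 5042 lower, 14 to 15 lists and Pfas from -1.23 to -0.97. Of the 112 other named genes over these settings, 3087 values kept their call, 28 no longer passed (6 genes: Cd4, Prnp, Col12a1, Abcc9, Aldh1a1 and Cnn2) and 3 were reversed; of 35 lists, 1004 kept their call, 21 no longer passed and 20 newly passed. The cause was not tested unless given. With the number as a replicate block, 4529 were higher and 4755 lower, with Pfas at -1.10 and 15 lists, but deviations of same-numbered libraries correlated at -0.096 to 0.198, and only numbers 2 and 4 matched their own best, so the numbers pair no libraries. A Y-linked covariate was not run, as its level ranged only 1.99-fold. Depth limits detection to 0.131 to 0.161 CPM for a count of 0.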

Other observations

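The lists in this part were all chosen after the report's results had been seen, though before their own values were computed; NRF2 targets already seen high (Slc7a11, Hmox1 and Fth1) were left out. NF-kB pathway members and feedback targets rose in 20 of 20 genes, with a median log2 fold change of 1.61 (camera adjusted p = 2.88e-16 over 7 lists; adjusted p = 0.00769 with an estimated correlation). Tnfaip3, a brake on NF-kB signalling, rose 7.55-fold, Traf1 6.64-fold and the NF-kB subunit gene Rel 3.90-fold (n = 6 each). NRF2 antioxidant targets rose in 15 of 15 genes, with a median of 1.31 (camera adjusted p = 1.94e-10; adjusted p = 0.00895 with an estimated correlation). Nqo1, a quinone reductase, rose 3.95-fold, Srxn1 3.42-fold and Gclc, which makes a glutathione precursor, 3.14-fold.

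Unfolded protein response genes had 9 up and 2 down of 16 (camera adjusted p = 0.0281; adjusted p = 0.193 with an estimated correlation), with a median of 0.24 that went to 0.00445 with library totals alone. Hspa5, a chaperone of the endoplasmic reticulum, rose 1.86-fold and Dnajb9 2.32-fold, while Pdia4 fell by 0.56 on the log2 scale. Lysosomal genes had 1 up and 12 down of 20 (camera adjusted p = 0.0515, and 0.0277 with near-identical libraries summed; adjusted p = 0.504 with an estimated correlation), with a median of -0.18, or -0.41 with library totals alone, and Mcoln1 at 0.637 of its control level. Fatty acid oxidation genes had 1 up and 10 down of 16 (adjusted p = 0.0762), among them Cpt1a, which admits fatty acids to mitochondria, at 0.637 of its control level, while Acadl rose 1.56-fold. Cholesterol genes had 5 up and 8 down of 18 (adjusted p = 0.421), and MHC class II genes 3 up and 1 down of 8 (adjusted p = 0.318), with H2-Eb1 up 2.50-fold.

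A hypothesis for the inflammatory genes is an NF-kB response that reaches beyond the cytokine genes. The NF-kB list, which shares 0 genes with the other lists, had a median of 1.611, as such a response would give. It was chosen after the rise of the cytokine genes was seen, and related genes can move together without sharing members. The list is therefore no independent test. Camera's comparison also does not tell a response to losing Pfas from one to handling or from a difference between separately processed libraries.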
